A study of Mus musculus with 15 samples.

How the data were processed

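RNA from the cortex of 5XFAD and non-transgenic control mice on the C57BL/6J background was sequenced at 3, 6 and 12 months of age, in 15 libraries that form 6 groups of genotype and age. Per the labels' protocols, libraries were made with a stranded total RNA kit after depletion of ribosomal RNA and read as pairs of 100 bases, while the molecule field of the same labels reads polyA RNA. The counts were deposited by the authors as raw whole numbers per Ensembl mouse gene, without normalization. Per the labels, CASAVA, STAR and BWA were the tools and mm9 the genome build, with no versions given. The counting program, the annotation release, the use of strand and the handling of reads shared between genes are not stated. Reads shared by near-identical copies (C4a and C4b, the H2 genes, the globin genes, Hspa1a and Hspa1b) leave the values of these genes uncertain. Symbols were matched by Ensembl identifier for 32919 of 37991 genes, which held 98.5% of the counts, and 5072 genes stayed without a symbol. No coordinates were used.

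Library totals ran from 105.2 M to 226.7 M counts. At this depth counting error is small for all but rare transcripts, and the spread between libraries sets the precision. Where a gene described here had 10 counts or fewer in a group, the ratio is given with its exact 95% Poisson interval, and against a group with 0 counts as a bound from a floor of 3 counts over the group. Intervals and floors cover counting error only. The labels do not say that the libraries come from separate animals, so the p-values measure the spread between these samples.

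Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the 6 groups, with a minimum count of 10 and a minimum total of 15, which left 21555 genes and removed 16436. TMM factors scaled the libraries, dispersions and the quasi-likelihood model were fitted with robust settings, and all 15 libraries entered 1 model with a coefficient per group, because groups of 2 or 3 libraries leave little information on their own. The prior count was 0.125. The SE of a log2 fold change was derived from the test, as its absolute value over the root of the F statistic. It is therefore approximate. There were 9 contrasts: 5XFAD against WT at each age, their average, the differences between the effects at 6 and 3, 12 and 6, and 12 and 3 months, and 12 against 3 months within each genotype. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, with no fold minimum. CPM are per TMM-scaled library and are given as mean and SD, except that Ttr, Drd2, Mbp, Xist and Y-linked genes, which describe the libraries, are per total count.

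The genes named were set by rule before the data were examined. They are transgene-related genes such as App and Thy1, the 10 largest increases and the 5 largest decreases per genotype contrast among called genes with a mean of at least 1 CPM and no overlap between the groups' values, up to 4 members of each list with the smallest p at 12 months, and the 5 largest changes in either direction for the other contrasts. Not every gene the rule picks is described. Ttr, Drd2, Mbp and Xist, which describe the libraries, were chosen after their values had been seen. Tle4 was named outside the rule, as were genes of the lists under other observations.

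There were 28 gene lists, written before the data were examined. They cover transgene-related genes, disease-associated and homeostatic microglia genes, complement, lysosomal, interferon-stimulated and antigen presentation genes, and reactive astrocyte genes. They also cover markers of astrocytes, oligodendrocytes and myelin, oligodendrocyte precursors, excitatory, layer 5 and inhibitory neurons, vasculature, meninges and choroid plexus, neighbouring regions, blood cells and peripheral leukocytes. The others hold synaptic, activity-dependent, plaque-associated extracellular protein, proliferation, cholesterol synthesis, oxidative phosphorylation (respiratory chain), unfolded protein response, heat shock and sex-linked genes. Each list was tested in 7 contrasts with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, and its members were also adjusted over the list alone. The transgene-related list was below the minimum of 5 members and was not tested as a list. Lists share members, Ctsd and B2m for example, and several microglial genes are also expressed by other cells of the cortex. Members that were found under neither the listed symbol nor a listed alias were not analysed here, while C1s, for example, was analysed as C1s1.

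Sexes were read from Xist and from Y-linked genes with a limit of 10 CPM. Libraries with Ttr above 100 CPM or Drd2 above 30 CPM were taken as rich in neighbouring tissue. Whether equal replicate numbers pair the libraries was checked from the correlation of deviations from group means over 12362 genes. It was 0.54, 0.2 and 0.19 at 6 months, above the limit of 0.1 for each of the 3 pairs, so the numbers were taken as pairs at that age from the data and not from the labels. The pair at 0.54 was male and the other pairs female, so sex and pair cannot be told apart there. The main model held no block for these pairs, so its p-values leave the pairing out, and the block is given as an alternative. The numbers at 3 and 12 months join 2 pairs each and were not taken as pairs, although the correlations at 3 months were 0.25 and 0.25.

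Alternatives were other size factors, library totals alone, no low-count filter and a stricter one at a mean of 1 CPM, the replicate number as a block, sex as a covariate, DESeq2 1.42.0 with its Wald test, models of the compared groups alone, each library left out in turn, and for lists camera with an estimated correlation and fry, which asks whether a list moves on balance in 1 direction. Female libraries alone, the libraries rich in neighbouring tissue left out, and thinning to the smallest total were added after the data had been seen. The methods were tested on simulated counts for the same genes and library sizes with 200 changed genes, where the share of false calls was 2.8% to 8.6% for edgeR and 18.8% to 25.3% for DESeq2. A check for samples far from their group was not made, since groups of 2 or 3 are too small for it.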

Results

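RNA was sequenced from the cortex of 5XFAD mice, a line that carries human transgenes with familial Alzheimer's disease mutations under a Thy1 promoter, and of non-transgenic C57BL/6J controls (WT). At 3 months there were 2 WT and 2 5XFAD libraries, at 6 months 3 and 3, and at 12 months 2 WT and 3 5XFAD, 15 in all. Total counts per library ran from 105.2 M to 226.7 M. The 5XFAD libraries were on average the deeper ones at each age, with means of 207.8 M against 173.3 M at 3 months, 180.6 M against 135.6 M at 6 months and 170.1 M against 110.2 M at 12 months. The table held 37991 genes, of which 21555 passed the low-count filter and were tested. Xist and Y-linked transcripts marked 10 libraries as female and 5 as male, the males being replicate 1 of both genotypes at 3 and at 6 months and replicate 1 of 5XFAD at 12 months. The 12-month WT group therefore held females alone. Transcripts of neighbouring tissue stood out in 4 libraries. Ttr, a transport protein made by the choroid plexus, was at 3720 CPM in 6-month 5XFAD replicate 2 and at 584 CPM in 6-month 5XFAD replicate 1, with the other libraries at 39.1 CPM or less. Drd2, a dopamine receptor gene of the striatum, was at 55.1 CPM in 3-month WT replicate 1 and at 36.5 CPM in 12-month 5XFAD replicate 3. Mbp, which encodes a myelin protein, ranged from 766 to 3810 CPM.

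**Figure D1:**
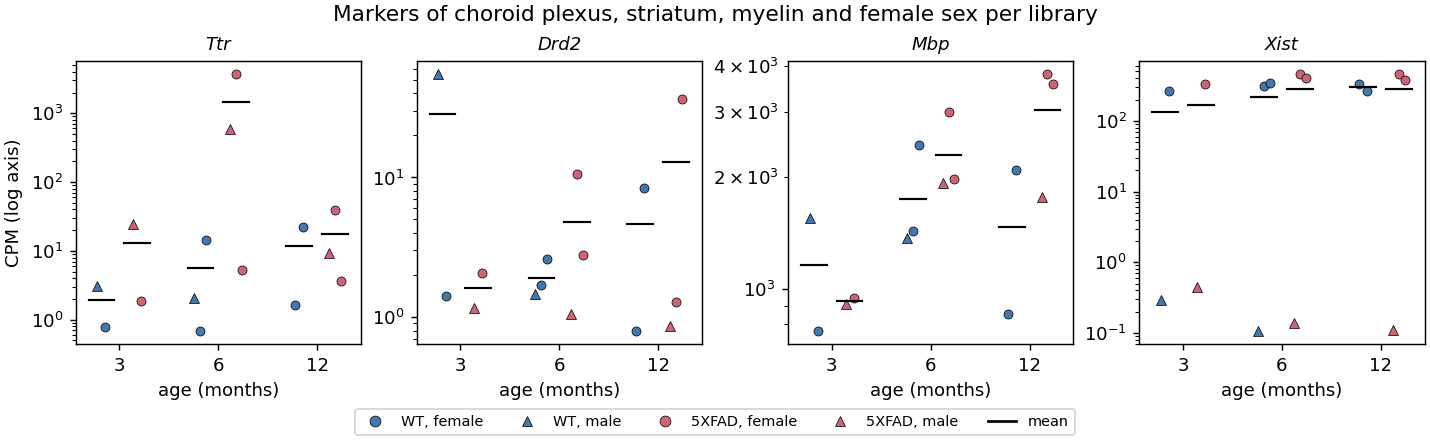
CPM (log axis) of Ttr, Drd2, Mbp and Xist in each of the 15 libraries, by age in months and genotype, with circles for female and triangles for male libraries and bars for group means. Ttr reached 3720 CPM and 584 CPM in 2 of the 6-month 5XFAD libraries, and Mbp reached 3810 CPM at 12 months.

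The transgenes gave a check of the labels. Thy1 separated the genotypes in all 15 libraries, at 552 to 699 CPM in WT and 2050 to 2630 CPM in 5XFAD. Its log2 fold change was 1.77 ± 0.13 (SE) at 3 months, 1.87 ± 0.11 at 6 months and 1.9 ± 0.13 at 12 months. The adjusted p of edgeR's quasi-likelihood test was 0.000104, 4.41e-06 and 2.38e-05 at these ages. App passed at none of these ages, with log2 fold changes of 0, 0.11 and 0.14 and edgeR adjusted p of 1, 0.665 and 0.499. Human transgene reads can align to mouse App and Thy1, and their share in these counts is not known.

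The comparison at 3 months asks what differed in young 5XFAD cortex. Thy1 was the 1 gene of 21555 that edgeR called. Beneath it, genes of plaque-associated microglia already lay higher in 5XFAD without passing over all genes. Clec7a, a phagocytic lectin receptor, was at 3.03 ± 0.598 CPM (SD, n = 2) against 0.0758 ± 0.0663 (n = 2), with an edgeR adjusted p of 0.0676. Itgax, an integrin of activated microglia, was at 2.64 ± 0.457 against 0.126 ± 0.0559 CPM, with an edgeR adjusted p of 0.144. Ccl3 and Ccl4, chemokine genes, had log2 fold changes of 3.04 ± 0.56 and 3.51 ± 0.57, the second on 144 counts against 10, a ratio of 11.7 with a 95% counting interval of 6.18 to 24.9. Gfap, the intermediate filament of astrocytes, was at 148 ± 0.483 against 78.9 ± 9.52 CPM.

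By list, 27 of the 28 disease-associated microglia genes at 3 months had a positive log2 fold change, with a median of 0.67. None was called by edgeR over all genes tested, and 7 were called higher when adjusted over the list alone. Camera placed the list above other genes at an adjusted p of 7.5e-14 (adjusted p = 0.488 with an estimated correlation). All 18 cholesterol synthesis genes were positive, with a median of 0.25 and 6 called higher when adjusted over the list alone, and the camera adjusted p was 1.08e-14 (adjusted p = 0.275 with an estimated correlation). Fdps, Nsdhl and Sqle, enzymes of that pathway, had log2 fold changes of 0.39 ± 0.1, 0.36 ± 0.1 and 0.3 ± 0.1. Interferon-stimulated genes had a median of 0.34 and antigen presentation genes one of 0.24, at camera adjusted p of 6.16e-06 and 0.000432 (adjusted p = 0.626 for both with an estimated correlation), the second being 0.108 without 5XFAD replicate 2. On the other side stood the unfolded protein response genes, with 14 of 16 negative, a median of -0.18 and a camera adjusted p of 4.93e-05 (adjusted p = 0.11 with an estimated correlation). All 12 heat shock genes were negative as well, with a median of -0.15 and a camera adjusted p of 0.000354 (adjusted p = 0.275 with an estimated correlation). The last list had an adjusted p of 0.527 without WT replicate 2, and the unfolded protein response list one of 0.0557 without 5XFAD replicate 1. Camera called 17 of 27 lists in all, and with an estimated correlation it called 0 at the adjusted threshold.

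Markers of neighbouring striatum differed with genotype at 3 months, where Drd2 was at 55.1 CPM in WT replicate 1 and at 1.42 CPM in WT replicate 2. The neighbouring region markers had a median of -0.74 and a camera adjusted p of 0.00241, which was 0.93 without WT replicate 1, 0.199 without 5XFAD replicate 1 and 0.626 with an estimated correlation. Activity-dependent genes, with a median of 0.27 and a camera adjusted p of 0.00241, and myelin markers, with a median of -0.31 and 0.0458, changed direction without that library, at adjusted p of 0.13 and 0.167; with an estimated correlation the adjusted p was 0.626 for the first list and 0.696 for the second. Without 5XFAD replicate 2 the adjusted p of these lists was 0.243 and 0.151, and myelin markers had 0.236 without 5XFAD replicate 1. At unadjusted p below 0.05 edgeR counted 497 genes, and DESeq2 called 14. The 497 are fewer than 0.05 of the 21555 genes tested, the share that chance alone gives on average. In simulated counts of the same depth and group sizes, edgeR recovered 60% of 2-fold and 83% of 4-fold changes at 3 months.

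At 6 months genes of plaque-associated microglia stood out. Cst7, a cystatin gene of plaque-associated microglia, was at 53.2 ± 38.2 CPM (SD, n = 3) in 5XFAD and 0.146 ± 0.108 (n = 3) in WT, a log2 fold change of 8.44 ± 0.74 (SE). Clec7a rose to 25 ± 14.4 from 0.245 ± 0.0791 CPM, Itgax to 23.7 ± 16.4 from 0.221 ± 0.0835 and Ccl6, a chemokine gene, to 19.8 ± 11.6 from 0.736 ± 0.135. Ccl3 and Ccl4 rose by 6.36 ± 0.51 and 6.99 ± 0.51 on the log2 scale. The other genes among the 10 largest increases were Pdcd1, which encodes the checkpoint receptor PD-1, Ly9, St14 and Gm49339, with log2 fold changes from 4.11 to 5.55. The edgeR adjusted p of these 10 genes lay between 4.03e-05 and 0.00428. Ccl4 rested on 8 counts over the 3 WT libraries against 1524 in 5XFAD, a ratio of 138 with a 95% counting interval of 69.8 to 320.

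In all, edgeR called 418 genes at 6 months, 402 higher and 16 lower in 5XFAD, and 315 of them differed at least 2-fold. The numbers higher and lower were 503 and 56 with the replicate number as a block and 765 and 91 by DESeq2. The 5 largest decreases were small beside the increases. Tmem40 fell by 1.43 on the log2 scale, Ranbp3l by 0.88, Sdk2 by 0.81, Opn3 by 0.78 and Ndst3 by 0.65, with edgeR adjusted p from 0.00927 to 0.049. Sdk2 encodes a synaptic adhesion molecule and Ndst3 a heparan sulfate modifying enzyme.

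Among the fixed lists at 6 months, 23 of the 28 disease-associated microglia genes rose, and 28 when adjusted over the list alone. Their median log2 fold change was 2.74 and the camera adjusted p 8.89e-41 (adjusted p = 0.0611 with an estimated correlation). Homeostatic microglia genes rose as well, 12 of 18, or 16 when adjusted over the list alone, with a median of 1.13 and a camera adjusted p of 1.24e-18 (adjusted p = 0.112 with an estimated correlation). Cx3cr1, the fractalkine receptor, went to 113 ± 37.7 from 50.6 ± 8.13 CPM. Of the lysosomal genes 17 of 30 rose, 23 when adjusted over the list alone, with a median of 0.68 and a camera adjusted p of 3.03e-26 (adjusted p = 0.0611 with an estimated correlation). The cathepsin genes Ctsd and Ctss were among them, at 1180 ± 530 against 317 ± 9.01 CPM and 213 ± 88.4 against 50.1 ± 6.64 CPM. Complement genes rose in 12 of 19 cases, or 14 adjusted over the list alone, with a median of 1.4 and a camera adjusted p of 5.21e-15 (adjusted p = 0.0762 with an estimated correlation). C4b, a component of the classical pathway, was at 215 ± 95.8 against 19.7 ± 4.19 CPM, and its near-identical copy C4a may share reads with it.

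Immune signalling genes moved the same way at 6 months. Of the interferon-stimulated genes 16 of 24 rose, and all 24 when adjusted over the list alone, with a median of 1.07 and a camera adjusted p of 7.19e-27 (adjusted p = 0.0611 with an estimated correlation). Ifit3 was at 15.8 ± 4.06 against 7.75 ± 0.999 CPM. Of the antigen presentation genes 13 of 18 rose, or 15 adjusted over the list alone, with a median of 1.37 and a camera adjusted p of 1.24e-18 (adjusted p = 0.0611 with an estimated correlation). Cd74, the MHC class II invariant chain, was at 22.2 ± 13.2 against 2.37 ± 0.466 CPM and B2m, the light chain of MHC class I, at 208 ± 54.8 against 73.1 ± 5.1.

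Genes of reactive astrocytes formed a second group at 6 months. Reactive astrocyte genes rose in 7 of 21 cases, or 12 adjusted over the list alone, with a median of 1.1 and a camera adjusted p of 3.13e-11 (adjusted p = 0.143 with an estimated correlation). Gfap was at 816 ± 275 CPM in 5XFAD and 82.1 ± 5.28 in WT. The astrocyte identity markers had 1 of 17 members called, Atp13a4, at an edgeR adjusted p of 0.0367 that was 0.0635 with the replicate number as a block; the list had a median of 0.11 and a camera adjusted p of 0.0618. Among cholesterol synthesis genes all 18 were positive, 3 rose over all genes tested and 14 when adjusted over the list alone. Their median was 0.3 and the camera adjusted p 2.22e-11 (adjusted p = 0.143 with an estimated correlation), with Nsdhl at 35.2 ± 3.66 against 25.4 ± 1.41 CPM and Fdps at 68.4 ± 6.35 against 51.5 ± 1.23.

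Neuronal lists lay slightly lower in 5XFAD at 6 months, with 0 members called by edgeR. Synaptic genes had a median of -0.15 and 25 of 28 negative members, at a camera adjusted p of 7.11e-06 (adjusted p = 0.3 with an estimated correlation). Their list mean of log2 CPM plus 1 overlapped between genotypes. It was 9, 8.97 and 8.78 in WT replicates 1, 2 and 3 and 8.92, 8.65 and 8.79 in 5XFAD. The lowest, 8.65, was in the 6-month library with the highest myelin list mean, 7.05. Whether carried-along tissue bears on the synaptic list at this age was not tested. Activity-dependent genes were negative in all 20 cases, with a median of -0.63 and a camera adjusted p of 4.83e-06 (adjusted p = 0.362 with an estimated correlation). Arc, an immediate early gene of synaptic plasticity, was at 270 ± 133 against 434 ± 154 CPM. Inhibitory neuron markers had a median of -0.18 and a camera adjusted p of 0.000232 (adjusted p = 0.169 with an estimated correlation), and layer 5 markers one of -0.25 and 0.00597 (adjusted p = 0.0611 with an estimated correlation). Excitatory neuron markers had a median of -0.08 and a camera adjusted p of 0.0411, which was 0.0566 with the replicate number as a block and 0.522 with an estimated correlation. The myelin list had a median of 0.33 and a camera adjusted p of 0.00491, and the proliferation list one of 0.32 and 0.0285; with an estimated correlation the adjusted p was 0.644 for the first and 0.58 for the second. The excitatory neuron list had an adjusted p of 0.189, 0.11, 0.372 and 0.11 without WT replicate 1 or 2 or 5XFAD replicate 2 or 3. The myelin list had 0.124, 0.0501 and 0.249 without WT replicate 1 or 2 or 5XFAD replicate 2, and the proliferation list 0.31 and 0.287 without WT replicate 1 or 5XFAD replicate 3. Without the 4 libraries rich in neighbouring tissue, an alternative chosen after seeing the data that leaves 1 5XFAD library at 6 months, activity-dependent genes had 0.228 and myelin markers 0.395.

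Choroid plexus transcripts were high at 6 months in the 2 5XFAD libraries rich in Ttr and not in replicate 3. The mean log2 CPM plus 1 of meningeal and choroid plexus markers was 2.96, 5.08 and 1.86 in 5XFAD replicates 1, 2 and 3 and 2, 2.2 and 2.09 in WT. The meningeal and choroid plexus list had a median of 1.29 and a camera adjusted p of 0.835, which was 0.00448 with the replicate number as a block, where neighbouring region markers also passed at 0.0143 against 0.107 without it. With an estimated correlation camera called 0 of 27 lists at 6 months, while fry called 9 of the 27 and camera with its preset correlation 15. The number of called genes was 145, 199 and 270 without WT replicate 1, 2 or 3, and 680 without 5XFAD replicate 1, and a model of the 6-month groups alone called 24 genes, against 856 by DESeq2. Of 44 genes called at 6 months and named by rule, 18, 14 and 10 were no longer called without WT replicate 1, 2 or 3, and 4, 6 and 7 without 5XFAD replicate 1, 2 or 3; 9 held in each of 11 alternatives, among them Thy1, Ccl3, Ccl4, Itgax, Clec7a and Gfap.

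**Figure D2:**
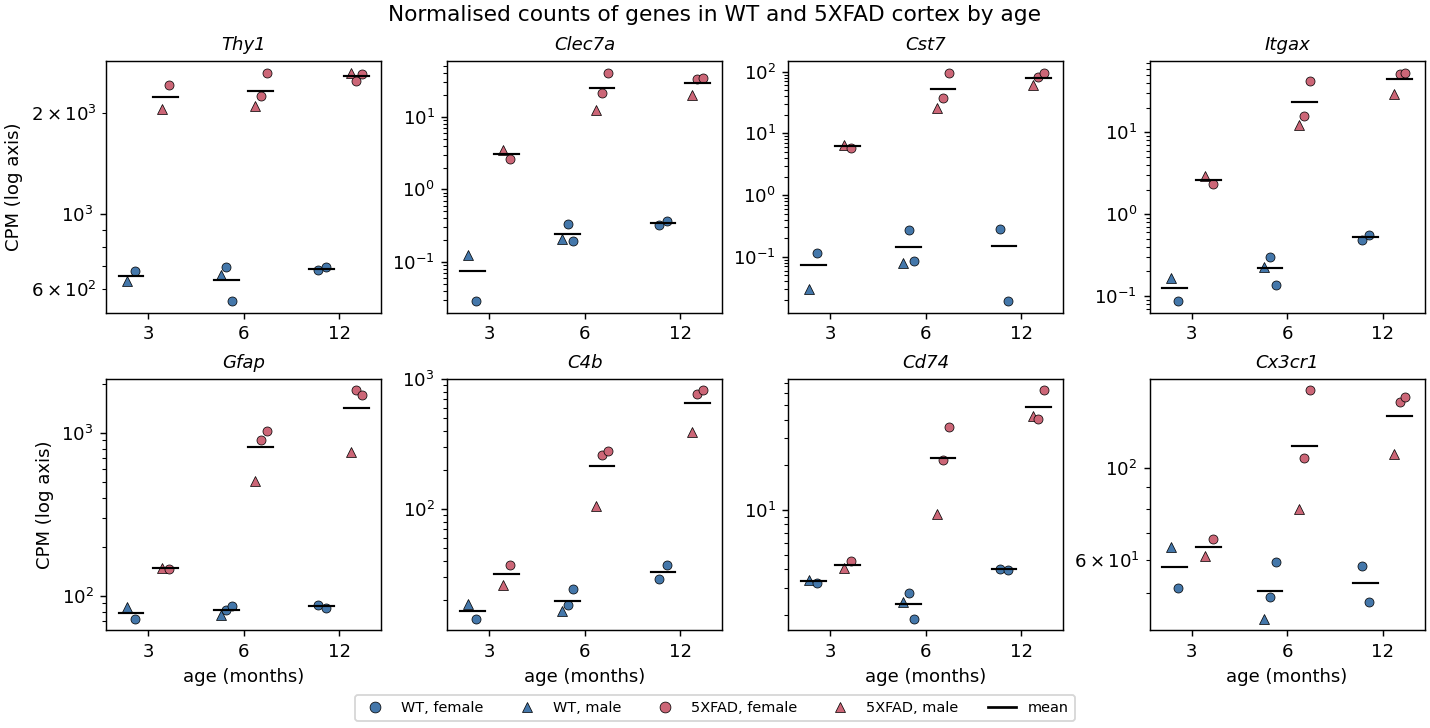
CPM (log axis) of Thy1, Clec7a, Cst7, Itgax, Gfap, C4b, Cd74 and Cx3cr1 in each library, by age in months and genotype, with circles for female and triangles for male libraries and bars for group means. Thy1 separated the genotypes at each age, while Gfap means in 5XFAD were 148, 816 and 1430 CPM at 3, 6 and 12 months.

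At 12 months the same kinds of genes led. Cst7 was at 79.8 ± 18.7 CPM (SD, n = 3) in 5XFAD and 0.151 ± 0.187 (n = 2) in WT, a log2 fold change of 8.99 ± 0.91 (SE). Itgax was at 45.2 ± 13.8 against 0.522 ± 0.0492 CPM and Clec7a at 29 ± 7.87 against 0.346 ± 0.0262. Ctse, which encodes cathepsin E, was at 2.11 ± 0.99 CPM in 5XFAD on 1139 counts against 2 counts over both WT libraries, a ratio of 238 with a 95% counting interval of 65.6 to 1960. Tnfsf8, which encodes the CD30 ligand, had 1286 against 3 counts, a ratio of 179 with an interval of 61 to 868. Ccl3, Ccl4, Pdcd1, Atp6v0d2, a subunit of the vacuolar proton pump, and Hcar2, a receptor for hydroxybutyrate and niacin, completed the 10 largest increases with log2 fold changes from 4.9 to 5.96. Ccl4 rested on 969 counts against 8, a ratio of 50.5 with an interval of 25.5 to 117. The edgeR adjusted p of these 10 genes lay between 0.00103 and 0.0188.

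In all, edgeR called 659 genes at 12 months, 590 higher and 69 lower, and 408 differed at least 2-fold. The numbers higher and lower were 700 and 41 with library totals alone, 552 and 103 with a stricter filter, and 1162 and 275 with the replicate number as a block. The largest decreases were those of D030055H07Rik, Nphs1, Kirrel2, Lars2 and 4930539E08Rik, which fell by 1.55, 1.25, 1.08, 1.06 and 1.03 on the log2 scale, with edgeR adjusted p from 0.0136 to 0.0322. Nphs1 and Kirrel2 are neighbouring genes of the nephrin family, and the use of strand in the counting is not stated, so reads of overlapping transcripts cannot be told apart. Lars2, the mitochondrial leucyl-tRNA synthetase, was at 119 ± 4.15 against 249 ± 75.8 CPM.

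All 28 disease-associated microglia genes rose at 12 months, with a median of 2.84 and a camera adjusted p of 2.31e-32 (adjusted p = 0.106 with an estimated correlation). Apoe, the apolipoprotein E gene, was among them at 1580 ± 304 against 908 ± 27.9 CPM, with an edgeR adjusted p of 0.0383 that was 0.269, 0.181, 0.125 and 0.114 without WT replicate 2 or 3 or 5XFAD replicate 2 or 3. Homeostatic microglia genes rose in 7 of 18 cases, while 14 were higher and 1 lower when adjusted over the list alone, with a median of 0.98 and a camera adjusted p of 2.84e-10 (adjusted p = 0.249 with an estimated correlation). Lysosomal genes rose in 20 of 30 cases, or 25 adjusted over the list alone, with a median of 0.77 and a camera adjusted p of 1.65e-21 (adjusted p = 0.106 with an estimated correlation). Complement genes rose in 11 of 19 cases, or 15 adjusted over the list alone, with a median of 1.38 and a camera adjusted p of 3.77e-14 (adjusted p = 0.106 with an estimated correlation). C4b was at 660 ± 235 against 32.9 ± 5.69 CPM.

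Interferon-stimulated genes rose in 19 of 24 cases at 12 months, and all 24 when adjusted over the list alone, with a median of 1.35 and a camera adjusted p of 8.89e-23 (adjusted p = 0.106 with an estimated correlation). Trim30a was at 9.69 ± 0.623 against 2.46 ± 0.0104 CPM. Antigen presentation genes rose in 14 of 18 cases, or 15 adjusted over the list alone, with a median of 1.45 and a camera adjusted p of 8.92e-17 (adjusted p = 0.106 with an estimated correlation). Cd74 was at 48.5 ± 12.5 against 4.01 ± 0.046 CPM and H2-Aa, an MHC class II chain, at 17 ± 4.95 against 1.5 ± 0.242. Leukocyte markers had a median of 1.19, which stayed at 1.19 with Cd3g set to its bound, and a camera adjusted p of 0.00206 (adjusted p = 0.249 with an estimated correlation). Over all genes 2 of 17 rose, and 3 when adjusted over the list alone. The list mean of log2 CPM plus 1 was 0.44, 0.37 and 0.68 in 5XFAD replicates 1, 2 and 3 against 0.31 and 0.34 in WT. Replicate 3 also had the highest mean of blood cell markers, at 5.15 against 4.61 and 4.04 in the other 5XFAD libraries and 4.76 and 4.51 in WT. Cd3g, a T cell receptor chain, had 139 counts in 5XFAD and 0 in WT, 19.3-fold higher against a floor of 3 counts over the WT group. The exact 95% counting interval of its ratio began lower, at 15.5. Nkg7, a cytotoxic granule gene, had 155 counts against 1, a ratio of 64.7 with a 95% counting interval of 11.4 to 2570. The edgeR adjusted p of Cd3g was 0.0135, and 0.128 and 0.114 without WT replicate 2 or 3, and that of Nkg7 was 0.0231, and 0.143, 0.173, 0.0688 and 0.0551 without WT replicate 2 or 3 or 5XFAD replicate 2 or 3.

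Reactive astrocyte genes rose in 8 of 21 cases at 12 months, or 16 adjusted over the list alone, with a median of 1.64 and a camera adjusted p of 3.77e-14 (adjusted p = 0.111 with an estimated correlation). Gfap was at 1430 ± 584 CPM in 5XFAD and 86.1 ± 2.02 in WT. Astrocyte markers rose in 2 of 17 cases, Atp13a4 and the bicarbonate transporter gene Slc4a4, and in 5 adjusted over the list alone, with a median of 0.27 and a camera adjusted p of 0.00012 (adjusted p = 0.249 with an estimated correlation). The myelin list had a median of 0.99 with all 20 members positive, 0 called over all genes and 3 adjusted over the list alone, at a camera adjusted p of 2.61e-09 (adjusted p = 0.301 with an estimated correlation). Cldn11, a tight junction gene of myelin, was at 189 ± 70.1 against 61.5 ± 34 CPM. Mbp, a member of this list, ran from 1770 to 3810 CPM in the 12-month 5XFAD libraries and was at 856 and 2090 CPM in WT.

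At 12 months synaptic genes again lay slightly lower, with a median of -0.19, 0 called over all genes and 2 lower when adjusted over the list alone, at a camera adjusted p of 3.22e-07 (adjusted p = 0.249 with an estimated correlation). The list mean of log2 CPM plus 1 was 8.93 and 8.84 in WT replicates 2 and 3 and 8.83, 8.74 and 8.59 in 5XFAD replicates 1, 2 and 3, where that of the myelin list was 5.47 and 6.39, and 6.36, 7.1 and 7.25. Syn1, a synaptic vesicle gene, was at 621 ± 77.6 against 839 ± 1.85 CPM, with an edgeR adjusted p of 0.0529. Excitatory neuron markers had a median of -0.2, with 2 lower when adjusted over the list alone and a camera adjusted p of 0.000899 (adjusted p = 0.249 with an estimated correlation). Slc17a7, a vesicular glutamate transporter gene, was at 1160 ± 142 against 1570 ± 2.93 CPM. Activity-dependent genes had a median of -0.5 and a camera adjusted p of 0.000295 (adjusted p = 0.468 with an estimated correlation), which was 0.0651 without 5XFAD replicate 3, and respiratory chain genes a median of -0.08 and 0.00198 (adjusted p = 0.496 with an estimated correlation), which was 0.148 without WT replicate 3.

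The remaining lists did not pass camera at 12 months in the main fit. With the replicate number as a block camera called 18 of 27 lists, against 14 in the main fit, so some of the remaining lists passed there. Their medians and adjusted p were 0.04 and 0.719 for layer 5 markers, -0.08 and 0.164 for inhibitory neuron markers, 0.26 and 0.08 for oligodendrocyte precursor markers, 0.11 and 0.08 for cholesterol synthesis genes, and 0.07 and 0.08 for unfolded protein response genes. They were -0.1 and 0.0871 for heat shock genes, 0.26 and 0.0923 for proliferation genes, 0.6 and 0.0572 for neighbouring region markers, and 0.37 and 0.537 for meningeal and choroid plexus markers. For vascular markers the median was 0.02 and the camera direction down at 0.897, for blood cell markers 0.14 and down at 0.723, and for plaque-associated extracellular protein genes -0.03 with a mean of 0.15 and the direction up at 0.861. Sex-linked genes had an adjusted p of 0.861. Of the plaque-associated extracellular protein genes 1 was called by edgeR, Apoe, and 5 rose when adjusted over the list alone. Of the unfolded protein response genes 1 was called, Sdf2l1, an endoplasmic reticulum chaperone cofactor, at 13 ± 1.56 against 7.63 ± 1.12 CPM. Among neighbouring region markers, of which 3 rose when adjusted over the list alone, Prox1, listed for the hippocampus, was called at 19.1 ± 4.75 against 9.41 ± 2.9 CPM. Without WT replicate 2 or 3 or 5XFAD replicate 2 or 3 the edgeR adjusted p of Sdf2l1 was 0.313, 0.109, 0.0672 and 0.103 in place of 0.0314, and that of Prox1 0.339, 0.0815, 0.145 and 0.101 in place of 0.0406.

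**Figure D3:**
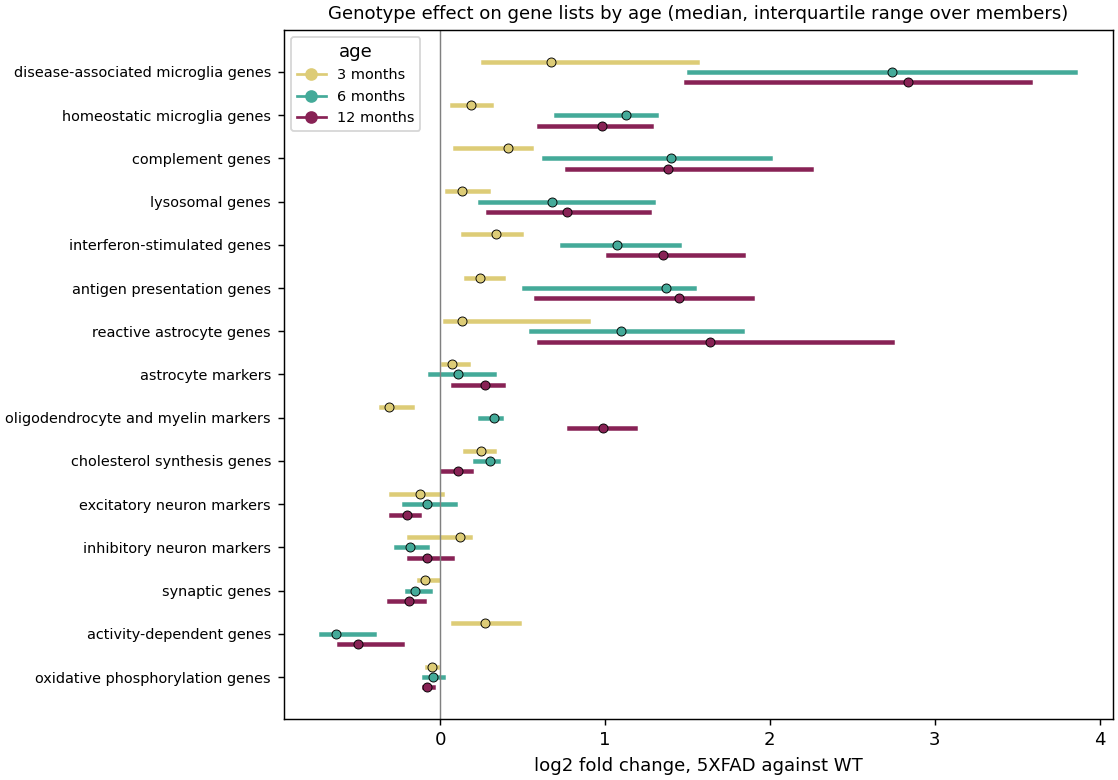
Median log2 fold change of 5XFAD against WT over the members of 15 gene lists at 3, 6 and 12 months, with bars for the interquartile range over members. The disease-associated microglia list lay at 0.67, 2.74 and 2.84, and the synaptic list at -0.19 at 12 months.

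Both WT libraries carried much of the 12-month result. The count of 659 genes became 22 without WT replicate 2 and 32 without WT replicate 3, 235 and 294 without 5XFAD replicate 2 or 3, and 1023 without the male 5XFAD replicate 1; with sex as a covariate it was 1162, in female libraries alone 1089 and by DESeq2 1494. Of 46 genes called at 12 months and named by rule, 38 and 35 were no longer called without WT replicate 2 or 3, and 1, 13 and 11 without 5XFAD replicate 1, 2 or 3; Thy1, Cst7, Itgax, Clec7a, Ccl3, Ccl4 and Gfap held in each of 10 alternatives.

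The overlap between ages asks whether the same genes were involved, in comparisons whose group means share no library. Both used the spread of each gene estimated from all 15 libraries, so genes of small spread are called more readily at both ages. The numbers expected for independent lists may therefore be too low. Of the 402 genes called higher at 6 months and the 590 at 12 months, 315 were in both, where independent lists would share 11. Of the 16 and 69 called lower, 5 were in both, where independent lists would share 0.0512 (Fisher's exact test, two-sided, p = 1.23e-09). This p-value treats genes as independent, which they are not, so it is a description only. The number lower in both was 31 with the replicate number as a block and 24 by DESeq2. Genes called higher at 12 months had a median log2 fold change of 0.18 at 3 months and 1.02 at 6 months, ages at which they were not selected. With the replicate number as a block these medians were 0.07 and 0.54, and by DESeq2 0.1 and 0.63. Genes called higher at 6 months had a median of 0.36 at 3 months and 1.53 at 12 months, the second being 1.19 by DESeq2. Genes called lower at 12 months had medians of -0.05 at 3 months and -0.22 at 6 months. Across the 21555 genes, which are not independent replicates, the log2 fold changes at 6 and 12 months correlated with Pearson's r of 0.44 and Spearman's rho of 0.47, those at 3 and 6 months with 0.13 and 0.07, and those at 3 and 12 months with 0.07 and 0.04.

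**Figure D4:**
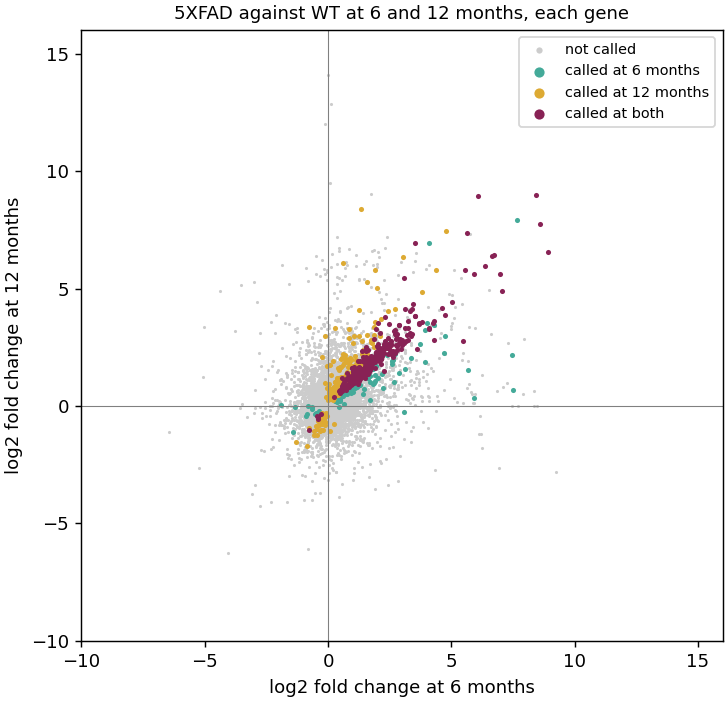
Log2 fold change of 5XFAD against WT at 6 months (horizontal axis) and 12 months (vertical axis) for each of 21555 genes, coloured by the age at which edgeR called them. Of the genes called, 315 were higher at both ages and 5 lower at both.

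Averaged over the 3 ages, 28 of 28 disease-associated microglia genes, 23 of 24 interferon-stimulated genes and 9 of 18 cholesterol synthesis genes rose in 5XFAD. Hsd17b7, Fdps, Sqle and Nsdhl of the sterol pathway had log2 fold changes from 0.27 to 0.34, and Syn1 fell by 0.26 (edgeR adjusted p = 0.0418). In all, edgeR called 870 genes, 762 higher and 108 lower, which became 1018 and 42 with library totals alone and 1129 and 327 with the replicate number as a block. The list medians were 2.13, 0.97 and 0.23 for the first 3 groups, with camera adjusted p of 1.19e-39, 1.14e-27 and 1.5e-10 (adjusted p = 0.0773, 0.0773 and 0.156 with an estimated correlation). The count was 500 without 3-month WT replicate 2, and 553 and 556 without 12-month WT replicate 2 or 3, 1404 with sex as a covariate and 1588 by DESeq2. Syn1 had an adjusted p from 0.0592 to 0.17 when 1 library was left out, except for 3-month WT replicate 1, 6-month WT replicate 3 and the male 5XFAD libraries at 6 and 12 months, and Hsd17b7, at 0.036 with all libraries, had 0.0581 to 0.0936 without any of 10 libraries.

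Whether the genotype effect itself changed with age was tested directly. At 12 against 6 months, 12 against 3 months and 6 against 3 months, edgeR called 0 genes, with 684, 2240 and 1161 at unadjusted p below 0.05, and DESeq2 called 0, 227 and 60. Chance alone gives on average 0.05 of the 21555 genes tested. The 684 lie below that share, and the 2240 and 1161 above it. For 12 against 3 months edgeR called 9 genes without 12-month 5XFAD replicate 1, 20 with the replicate number as a block and 24 in a model of the compared groups alone. For 6 against 3 months it called 34 without 6-month 5XFAD replicate 1. In simulated counts edgeR recovered 45%, 38% and 43% of 2-fold differences in effect for these contrasts. Camera called 6 lists between 6 and 12 months. The myelin list had a difference of 0.67 in median log2 effect, reactive astrocyte genes 0.52, leukocyte markers 0.7, interferon-stimulated genes 0.22 and astrocyte markers 0.17, and cholesterol synthesis genes -0.17. The camera adjusted p were 3.67e-06, 0.00279, 0.0254, 0.0276, 0.00707 and 3.38e-06, and the adjusted p = 0.883 for each of the 6 lists with an estimated correlation. Without the 4 libraries rich in neighbouring tissue, an alternative chosen after seeing the data that leaves 1 5XFAD library at 6 months, the interferon list turned direction at an adjusted p of 0.738, and the lists of reactive astrocyte genes, astrocyte markers and leukocyte markers had adjusted p of 0.127, 0.249 and 0.648. The myelin list had an adjusted p of 0.444 without 12-month WT replicate 2, and reactive astrocyte genes had 0.224 without 6-month 5XFAD replicate 1. Interferon-stimulated genes had 0.0925, 0.123 and 0.994 without 6-month WT replicate 2 or 3 or 5XFAD replicate 1, and 0.314 and 0.0565 without 12-month WT replicate 3 or 5XFAD replicate 1. Astrocyte markers had 0.228, 0.0507 and 0.0569 without 6-month WT replicate 3, 6-month 5XFAD replicate 2 or 12-month WT replicate 2. Leukocyte markers had 0.051 to 0.162 without any of 7 libraries, which were WT replicates 2 and 3 at both ages, 6-month 5XFAD replicates 1 and 2 and 12-month 5XFAD replicate 3.

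Age within each genotype was compared between 3 and 12 months. In 5XFAD, edgeR called 407 genes, 355 higher and 52 lower at 12 months. Atp6v0d2 had the largest increase, to 2.96 ± 1.33 (SD, n = 3) from 0.0172 ± 0.011 CPM (n = 2), on 1596 counts against 7, a ratio of 181 with a 95% counting interval of 87.8 to 452. It was followed by Ctse, C4b, Hcar2 and Gpnmb, a lysosomal glycoprotein gene, with log2 fold changes from 4.34 to 5.21. Gfap rose to 1430 ± 584 from 148 ± 0.483 CPM and Cd74 to 48.5 ± 12.5 from 4.32 ± 0.332. The largest decreases were those of D030055H07Rik, Muc6, C130026L21Rik, Efcab6 and Nphs1, which fell by 1.16 to 1.59 on the log2 scale. Of the disease-associated microglia genes 22 of 28 rose, and all 28 when adjusted over the list alone, with a median of 2.08 and a camera adjusted p of 2.8e-32 (adjusted p = 0.139 with an estimated correlation). Myelin genes had a median of 1.58, with 3 of 20 called, among them the transferrin gene Trf and Opalin, and 19 adjusted over the list alone, at a camera adjusted p of 1.37e-16 (adjusted p = 0.221 with an estimated correlation). Activity-dependent genes had a median of -0.84 and a camera adjusted p of 4.83e-09 (adjusted p = 0.301 with an estimated correlation). Camk2a, a kinase of excitatory synapses, fell by 0.44 and Dlg4, a postsynaptic scaffold gene, by 0.41, at edgeR adjusted p of 0.0458 and 0.0474, while Tle4, listed with Camk2a as an excitatory neuron marker, rose by 0.49 (adjusted p = 0.04). The excitatory neuron list had a camera adjusted p of 0.112 and the synaptic list, which holds Dlg4, 0.000587 (adjusted p = 0.716 and 0.521 with an estimated correlation). Neighbouring region markers had a mean log2 CPM plus 1 of 3.21 and 3.23 in the 3-month 5XFAD libraries. In 12-month replicates 1, 2 and 3 it was 3.24, 3.34 and 4.5, so tissue differed here as well. All 40 genes called and named by rule were lost without either 3-month library or without 12-month replicate 2, 35 without replicate 3 and 1 without replicate 1. The count was 0 without either 3-month library, 1 and 13 without 12-month replicate 2 or 3, and 832 without the male replicate 1, so the number of called genes rests on single libraries; DESeq2 called 1451.

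In WT, edgeR called 1 gene between 3 and 12 months, Nlrp5-ps, at 3.06 ± 0.406 (SD, n = 2) against 0.667 ± 0.0368 CPM (n = 2) and an adjusted p of 0.0358. Its adjusted p was 0.85 and 0.292 without 3-month replicate 1 or 2, and 0.447 and 0.14 without 12-month replicate 2 or 3. With 1256 genes at unadjusted p below 0.05 DESeq2 called 26. Cholesterol synthesis genes had a median of 0.2, with 5 of 18 higher when adjusted over the list alone and a camera adjusted p of 3.07e-11 (adjusted p = 0.57 with an estimated correlation). Unfolded protein response genes had a median of -0.28, with 6 of 16 lower when adjusted over the list alone and a camera adjusted p of 6.65e-06 (adjusted p = 0.0552 with an estimated correlation). Disease-associated microglia genes had a median of 0.24 and a camera adjusted p of 0.0752. Camera called 8 of 27 lists in WT. The mean log2 CPM plus 1 of neighbouring region markers was 4.64 and 3.24 in WT replicates 1 and 2 at 3 months, and 3.11 and 3.62 in replicates 2 and 3 at 12 months, so neighbouring tissue differed between the compared libraries. In simulated counts edgeR recovered 49% of 2-fold changes in WT and 59% in 5XFAD.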

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

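The tests of depth, neighbouring tissue, uneven sexes, more microglia and white matter, and those of the difference between ages for unfolded protein response genes, were chosen after the data or the result had been seen, as were the splits that keep pairs; the other splits were set before.

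In a test of the difference itself, the genotype effect differed between 6 and 12 months for 6 lists by camera with its preset correlation. It was larger at 12 months by a median of 0.22 on the log2 scale for interferon-stimulated genes (adjusted p = 0.0276), 0.52 for reactive astrocyte genes (0.00279), 0.17 for astrocyte markers (0.00707), 0.67 for myelin markers (3.67e-06) and 0.7 for leukocyte markers (0.0254). It was smaller for cholesterol synthesis genes, at -0.17 (3.38e-06). With an estimated correlation the adjusted p was 0.883 for each of these lists, fry called 0 lists and edgeR called 0 genes. Several of these lists no longer passed when single libraries or those rich in neighbouring tissue were left out, as given with the results.

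For 3 further items the libraries of 1 age all moved one way and those of another age all the opposite way. The mean log2 CPM plus 1 of unfolded protein response genes differed by -0.16 at 3 months, 0.14 at 6 months and 0.2 at 12 months, so that the effect was 0.3 and 0.36 higher at the later ages (camera adjusted p = 2.36e-05 and 0.000102, and 0.113 and 0.183 with an estimated correlation). The list is given here because of this pattern, so these p-values are no independent evidence. From 3 to 12 months its median changed by -0.28 in WT and 0.07 in 5XFAD, so the shift between these ages lies mostly in WT. On the same scale Ranbp3l had differences of 0.11, -0.73 and -0.34, a change of -0.83 from 3 to 6 months and -0.45 from 3 to 12 months. The estimates of edgeR for these changes were -1.006 and -0.534 (adjusted p = 0.702 and 0.497). Sdf2l1 had -0.32, 0.54 and 0.7, a change of 0.86 and 1.02, with edgeR estimates of 0.969 and 1.112 (adjusted p = 0.702 and 0.279).

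Most genes called at 6 and 12 months were higher in 5XFAD. Deeper 5XFAD libraries would give such an excess only if it shrank at equal depth. With every library thinned to the smallest total, 84.9% of the calls at 12 months were higher in 5XFAD, against 89.5% at full depth, which argues against depth as the whole cause. Choroid plexus transcripts would put the 3 6-month 5XFAD libraries in the order of their Ttr. Of the 402 genes called higher at 6 months, 0.7% followed this order, and 350 were highest in the library with the least Ttr. Chance gives 16.7% for a single gene, but these genes vary together, so the shares are a description and no test. With the 4 libraries carrying choroid plexus or striatal transcripts left out, which leaves 2 WT and 2 5XFAD libraries at 12 months, the median log2 fold change of the genes called higher at 12 months was 1.24 against 1.31. The genes called higher at 6 months thus mostly did not follow Ttr, which says nothing of genes that were not called. Those called higher at 12 months were selected with the kept libraries included. A large fall of their median was unlikely beforehand, so it does not decide on neighbouring tissue. With female libraries alone, the median at 12 months was 1.42 against 1.31. No male library entered this value. Its genes were selected with the same female libraries included, so it does not decide on the uneven sexes. The 6 libraries at 6 months form 10 splits, too few for a share under 0.05; the real split gave 418 calls and the highest other 0. For the average over ages, 1 of 100 splits within ages, the real one, gave as many calls, with 870 against 0 for the highest other drawn. These splits break the 6-month pairs of equal replicate numbers. With the pairs kept at 6 months, 2 of 100 splits gave as many calls, with 870 for the real one and 1214 for the highest other, or 959 and 1395 with the pairs as a block. That other split exchanged replicate 1 between the genotypes at 3 months alone. For the average over ages these shares lie under 0.05, which argues against chance in the grouping as the cause without excluding it. With the pairs kept, a split other than the real one gave more calls, so the number of calls does not single out the real grouping. The splits at 6 months are too few to tell and those at 12 months were not run. A response of cortical glia and immune cells to the genotype remains a hypothesis, because it was found and tested on the same libraries.

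Disease-associated microglia genes rose more than homeostatic ones. If 5XFAD cortex held more microglia with unchanged expression per cell, both lists would rise alike. In the 12-month 5XFAD libraries the mean difference from WT in log2 CPM plus 1, a scale on which rare transcripts count less, was 2.22 ± 0.32 (SD, n = 3) for the first list and 0.82 ± 0.23 for the second, and the gap within a library was 1.4 ± 0.09. The mean log2 fold changes of edgeR were 3.04 and 0.87. Of the 28 disease-associated genes, 20 lay above 1.69, the largest homeostatic log2 fold change. A rise in cell number alone therefore leaves the gap unexplained, while more microglia together with a changed state may explain both rises. Entry of other myeloid cells and expression of some of these genes by other cells stay open, as bulk RNA does not separate them.

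Myelin genes were higher in 5XFAD at 12 months as a list. White matter carried along with the cortex to a different extent may explain this. The list mean of log2 CPM plus 1 ranged over 1.36 among WT libraries of all ages, more than the genotype difference of 0.97 at 12 months. At 12 months alone it was 5.47 and 6.39 in WT and 6.36, 7.1 and 7.25 in 5XFAD. The range is one of single libraries over ages and the difference one of group means, so the comparison does not settle the question. The genotype difference averaged over ages, 0.38, had an exact permutation p of 0.171 (two-sided, 1200 splits within ages), which does not test the 12 months alone. Among the 12-month libraries the synaptic list mean was lowest, at 8.59, where the myelin list mean was highest, at 7.25, so white matter may bear on the synaptic list as well. A change in oligodendrocytes with genotype or age stays open beside it and was not tested separately.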

How the results depend on the processing

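Female libraries alone, the 4 libraries rich in neighbouring tissue left out and thinning to the smallest total were alternatives chosen after the data had been seen; the others were set before. Female libraries alone leave 1 WT and 1 5XFAD library at 3 months. Without the libraries rich in neighbouring tissue 1 WT library is left at 3 months and 1 5XFAD library at 6 months, so values of these settings at these ages rest on single libraries.

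For lists, 2226 values stayed on their side of the threshold, 136 passed it newly and 228 no longer passed it, while 29 turned direction with a call in the main setting or the alternative. Turns of direction without any call count among the values that stayed, here and for named genes, and are not listed below. For named genes these numbers were 7109, 188, 423 and 0. Of the counts, 219 stayed within 1.5 times and 85 did not. With other size factors the calls at 6 and 12 months were 414 and 644, of which 412 and 635 were shared with those under TMM, and with library totals alone 466 and 741, of which 413 and 631 were shared. The totals gave 455 higher and 11 lower calls at 6 months.

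DESeq2 called 14 genes at 3 months, 856 at 6 months, 1494 at 12 months, 1588 for the average, 60 for 6 against 3 months, 227 for 12 against 3 months, 26 for age in WT and 1451 for age in 5XFAD. It included 418 of 418 genes called by edgeR at 6 months and 654 of 659 at 12 months. With its calls 543 genes were higher at both ages and 24 lower, genes called higher at 6 months had a median of 1.19 at 12 months, and those called higher at 12 months one of 0.63 at 6 months. Its share of false calls in simulated counts was larger; the cause on these data was not tested.

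With the replicate number as a block within ages there were 3 calls at 3 months, 559 at 6, 1437 at 12 and 1456 for the average, and 16 lists between 6 and 12 months. The lower overlap was 31, and the medians were -0.42 at 12 months for genes called lower at 6, and 0.07 at 3 months and 0.54 at 6 months for those called higher at 12. As a block across ages the number gave 20 calls for 12 against 3 months and 0 for age in WT. Correlations of equal numbers were 0.25 and 0.25 at 3 months and -0.06 and 0.13 at 12 months, where 1 library correlated best with another number. At 6 months the block ended or added no call of a list beyond those given with the results, ended, among the genes named in these texts, the call of Atp13a4, and added calls of Aqp4, S100b, Neurod6, Prkcd, Sdf2l1 and Atf3. The block within ages was not run for lists in the contrasts of age, because it cannot be told from age there.

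Sex as a covariate gave 1162 calls at 12 months, 1404 for the average, 0 for age in WT and 632 for age in 5XFAD. Female libraries alone gave 0 at 3 months, 1089 at 12, 2 for 6 against 3, 4 for 12 against 3, 0 for age in WT and 11 lists between 6 and 12 months. Without the libraries rich in neighbouring tissue there were 4 calls at 3 months, 40 for 6 against 3, 1 for 12 against 3 and 0 for age in WT. Thinning gave 0 for age in WT. The stricter filter gave 3 at 3 months, and no filter gave 1 for 12 against 3 months. Models of the compared groups alone gave 4 at 3 months, 24 at 6, 24 for 12 against 3 months and 0 for age in WT, with fewer libraries behind the spread. Apart from fewer libraries, the cause was not tested.

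By camera with an estimated correlation, 0 lists were called in each of the 7 contrasts. Fry called 0 at 3 months, 9 at 6, 9 at 12, 14 for the average, 0 for 12 against 6, 1 for age in WT and 7 for age in 5XFAD.

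Leaving out 1 library, where a lone library is assumed to vary like the other groups, gave 1 to 2 calls at 3 months, 145 to 680 at 6, 22 to 1023 at 12, 500 to 1248 for the average, 0 to 34 for 6 against 3, 0 to 9 for 12 against 3, 0 to 0 for 12 against 6 and for age in WT, and 0 to 832 for age in 5XFAD. The numbers of lists were 9 to 15, 12 to 17, 15 to 19 and 18 to 19 for the genotype contrasts, 4 to 14 for 12 against 6, 3 to 8 for age in WT and 10 to 16 for age in 5XFAD. The highest numbers at 6 and 12 months and for age in 5XFAD came without the male 5XFAD library, for which the cause was not tested.

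Lists that turned direction at 3 months were myelin markers (adjusted p = 0.124 without the neighbouring-tissue libraries, 0.311 in females, 0.167 without WT replicate 1), activity-dependent genes (0.0847, 0.921 and 0.13 under the same settings), neighbouring region markers (0.675 in females), astrocyte markers (0.715) and vascular markers (0.0202) without WT replicate 2, and sex-linked genes (0.00405) without 5XFAD replicate 2. At 6 months meningeal and choroid plexus markers turned at 0.00258 without the neighbouring-tissue libraries. Between 6 and 12 months those libraries, left out, turned disease-associated microglia (1.59e-10), lysosomal (8.41e-09), interferon-stimulated (0.738), antigen presentation (0.0061) and proliferation genes (0.0181). There the meningeal list turned with the block (0.017) and without 6-month 5XFAD replicate 3 (0.0413), as did homeostatic microglia genes without the same library (0.0471) and activity-dependent genes without 12-month 5XFAD replicate 3 (0.0471). For age in WT, vascular markers (0.948) and neighbouring region markers (0.517) turned without the neighbouring-tissue libraries, vascular markers in females (0.904), and both without 3-month replicate 1 (0.927 and 0.978). Myelin markers turned without 3-month replicate 2 (0.568) or 12-month replicate 3 (0.129), and activity-dependent genes without 3-month replicate 2 (0.00172). For age in 5XFAD, blood cell markers turned without 12-month replicate 2 (0.0381). The cause was not tested.

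For these lists the adjusted p with 1 library left out ranged, at 3 months, from 1.87e-06 to 0.236 for myelin markers, 2.64e-09 to 0.243 for activity-dependent genes, 1.25e-05 to 0.715 for astrocyte markers, 0.000308 to 0.644 for vascular markers and 0.00342 to 0.93 for sex-linked genes. Between 6 and 12 months it ranged from 0.00683 to 0.994 for meningeal, 0.00092 to 0.936 for homeostatic microglia and 0.0471 to 0.928 for activity-dependent genes. For age in WT it ranged from 8.2e-07 to 0.927 for vascular, 1.49e-07 to 0.978 for neighbouring region, 2.43e-09 to 0.568 for myelin and 0.000262 to 0.979 for activity-dependent genes, and for age in 5XFAD from 0.0381 to 0.997 for blood cell markers.

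Thinned to the smallest total, the libraries gave 410 calls at 6 months and 634 at 12 months, of which 385 and 594 were shared with those at full depth. In simulated counts edgeR recovered 54% of 2-fold changes at 6 months and 59% at 12 months, and 38% of 2-fold differences between the effects at 12 and 3 months.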

Other observations

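The test of sex and both lists of this part were chosen after the result was seen.

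Orthologues of late-onset Alzheimer's disease risk genes, a list of 23 written after gene values had been seen, had 7 members called higher by edgeR at 6 months and 8 at 12 months, and 0 lower. Their median log2 fold change was 0.39 and 0.34, with camera adjusted p of 1.86e-07 and 2.62e-07 (adjusted p = 0.0874 and 0.0924 with an estimated correlation). Trem2, the microglial receptor gene, rose by 2.8 ± 0.32 (SE) and 2.9 ± 0.38 on the log2 scale. Spi1, Abi3, Grn, Cd33 and Inpp5d were called at both ages, Plcg2 at 6 months, and Apoe and Rin3 at 12 months. Most of these genes are expressed by microglia, so the list overlaps in content with the microglia lists.

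Genes of the secretases that process the amyloid precursor and of proteases that degrade amyloid, 14 in all, had 0 members called by edgeR at 6 or 12 months. Their median log2 fold changes were 0.03 and 0.1, and the camera adjusted p 0.339 and 0.0917. Averaged over ages, Adam17, an alpha-secretase gene, was called at 0.37 ± 0.09 (adjusted p = 0.033).

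The microglial response may be larger in female 5XFAD mice. Female 5XFAD libraries lay above the male one on the disease-associated microglia list at 3 of 3 ages, by 0.07, 0.84 and 0.54 in mean log2 CPM plus 1 at 3, 6 and 12 months. In a model with a genotype by sex term, 26 of 28 list members were lower in males, with a median term of -0.46, while edgeR called 0 genes, with 547 at unadjusted p below 0.05. These 547 are fewer than 0.05 of the 21555 genes tested, the share that chance alone gives on average. Each 5XFAD group held 1 male, which was replicate 1 throughout, so sex cannot be told apart from what else sets replicate 1 apart.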
